A study of Homo sapiens with 4 samples.

How the data were processed

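Gene expression was measured in 4 samples of the SW480 colon adenocarcinoma line, 2 with MACC1 overexpression and 2 with a vector control, grouped as the sample labels name them. Per the labels' protocols, cells were grown in serum-containing medium, RNA was isolated on silica columns with DNase treatment, and Cy3-labelled cRNA was made by linear amplification for 1-colour hybridisation. Per the file headers, all 4 arrays were on 1 slide with 1 scan time and were read in 1 scan channel, so slide and scan cannot separate the groups and a fit with slide as a block was not run. Agilent Feature Extraction 9.1.3.1 quantified the scans, per the submitters' processing notes. The deposited scanner files hold intensity values per spot: a mean and a local background, and a processed signal from which, per the file headers, the software had subtracted background and a spatial trend and replaced signals near background by a surrogate value. Deposited beside them is the authors' table of log2 values, 1 column per sample. How it was made is not given in the sources used here; its 4 columns share 1 median of 7.36 and 1 minimum of 5.66, as quantile normalization with a floor would leave them. Its values followed log2 of the processed intensity of the same array (r between 0.991 and 0.997 across spots), so its scale is log2, and it was used as an alternative.

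Each array held 45015 spots, of which 43376 were not controls and represented 41000 probes. Spots marked as non-uniform or as population outliers were left out (183 and 70 on MACC1 replicates 1 and 2, 41 and 91 on vector replicates 1 and 2); saturation was marked on 0, 0, 0 and 2 spots. Log2 of the processed signal was averaged over the spots of a probe, and the 75th percentile over non-control probes was subtracted on each array. That percentile was 1186, 1312, 1552 and 1121 intensity units on MACC1 replicates 1 and 2 and vector replicates 1 and 2. A probe was tested if it was well above background on both arrays of at least 1 group and unflagged on all 4, which left 20458 probes. A gene was represented by its probe with the highest mean level over the 4 arrays. Of the 41000 probes, 23434 were named through their accession, 2317 through a current symbol and 1043 through an older symbol in a gene table of assembly GRCh38.p14; 14206 kept the name in the files. No genome build is named in the files, so no positions are given, and the table served only for names and gene order.

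The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 2.42 prior degrees of freedom. Where a probe was not well above background on any array of a group, only a bound is given: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, as normalized log2 values. Where a gene had several tested probes, the named genes were checked for disagreement: 21 other probes of 15 named genes were tested, and 3, all of ACTB, had the opposite sign without passing the test.

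Before the data were examined, 23 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule takes MACC1; SPON2, S100P, MET, TSPAN8 and LGR5; the 15 highest and 15 lowest called genes with a gene symbol whose brighter group lay above the median level of all tested genes; up to 4 called members of each list with the largest difference; and the control genes ACTB, GAPDH, TBP and HPRT1. A few genes that the rule names are not reported here. Lists with at least 5 tested members (19) were tested against the other genes with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with the correlation estimated and fry, which tests whether a list moves one way without comparing it with other genes, were alternatives. Other alternatives were normexp on the mean and background signals with an offset of 50, quantile normalization, median centring, the authors' table, 2 other filters on dim probes, the mean of a gene's probes, every probe on its own, flagged spots kept, 2 other variance priors, the replicate number as a block, each array left out, and thresholds of 0.1 and 0.01.

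An area of low signal was sought on each array. A spot's level minus the median of the other 3 arrays was smoothed by a median over a window of 8 rows and 3 columns to each side, with at least 8 usable spots, and a local median below -1 marked the area. Leaving out its probes was an alternative chosen after seeing the data. The steps were tested on simulated data for the MACC1 against vector comparison, with 15731 genes, their real mean levels and variances drawn from the fitted prior. With 200 genes changed, 0% of those changed 2-fold or 4-fold, 60% of those changed 16-fold and 92% of those changed 64-fold were recovered, with 4 false calls among 80. With 1573 genes changed, 4.57%, 65.7%, 92.4% and 97.0% were recovered at 2-fold, 4-fold, 16-fold and 64-fold, with 54 false calls among 1074. The simulation gave all 4 arrays the same spread and let genes vary independently. In the data the MACC1 pair spread more than the vector pair, so these rates may not carry over. A list of genes raised 2.83-fold was found by camera with the preset correlation, which also called 1 unchanged list, and by fry. Camera with an estimated correlation missed it, so a list that this setting does not call may still be shifted. A block of spots made 4-fold dimmer was found at 95.4% of its spots.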

Results

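SW480 cells, an established line from a human colon adenocarcinoma, were compared in a form made to overexpress MACC1 and in a form carrying the vector alone. MACC1 (metastasis associated in colon cancer 1) is known as a transcriptional activator of the MET receptor gene, and the comparison asked which other genes depend on its level in colorectal cancer cells. Total RNA of 2 MACC1 samples and 2 vector samples was labelled with Cy3 and hybridised to 1-colour whole-genome oligonucleotide arrays, 1 array per sample. The labels call the 2 samples of each group biological replicates and do not say whether they came from separate cultures, so the p-values measure the spread between these samples, which may be in part technical. Of 41000 probes, 46.8% and 55.7% were well above background on MACC1 replicates 1 and 2, and 55.0% and 47.0% on vector replicates 1 and 2. After the filter on dim probes 15731 genes were tested. The small number of arrays limits the precision of every value, and an exact permutation of 2 samples against 2 cannot give a two-sided p below 0.333.

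The MACC1 transcript was higher in the cells labelled as overexpressing it. Its probe, listed under the older name 7A5, lay at a mean log2 level of -1.09 ± 0.32 (SD, n = 2) relative to the 75th percentile of the array in MACC1 cells. It was not well above background on either vector array, where the mean was -5.88 ± 0.66 (SD, n = 2). The difference corresponded to at least 7.19-fold more signal (limma adjusted p = 0.0159). Whether the probe lies within the introduced sequence was not checked, so it may report the introduced or the cells' own MACC1. With another background correction, normexp, the computed log2 difference was 1.95, also against vector signal near background, and the adjusted p was 0.0762. The bounds printed as "at least" hold for the mean of 2 arrays under the main background correction only: with normexp, 28 of the 30 named genes with a bound differed by less than it. MET, which encodes the receptor of hepatocyte growth factor, rose 7.94-fold (log2 difference 2.99 ± 0.27 SE, adjusted p = 0.0169), and 2 further MET probes rose by 2.29 and 3.13 on the log2 scale.

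Secreted and surface proteins that have been linked to MACC1 were among the genes that rose most. SPON2, a secreted matrix protein, rose 130-fold (log2 difference 7.02 ± 0.63 SE, adjusted p = 0.0168; 236-fold without MACC1 replicate 1 and 71.2-fold without replicate 2), with 1 of the 2 vector arrays well above background. S100P, a calcium-binding protein of many carcinomas, rose 94.4-fold (6.56 ± 0.44 SE, adjusted p = 0.0138). The tetraspanin gene TSPAN8 was at least 29.6-fold higher (limma adjusted p = 0.0265) and was not well above background in vector cells. With normexp its log2 difference was 4.05, below that bound (limma adjusted p = 0.0639). The bound was 64.8-fold without MACC1 replicate 1 and 13.5-fold without replicate 2. POU5F1, a pluripotency factor with closely related pseudogenes that its probe may also detect, rose 12.9-fold (adjusted p = 0.0138). LGR5, a receptor of intestinal stem cells, was not well above background on any of the 4 arrays. Of the 15 genes of the fixed list of MACC1-linked genes 10 passed the filter on dim probes and were tested. Of these 6 rose, 1 fell and 3 did not pass the test, and the counts were also 6 and 1 when adjusted over the list alone. A gene can pass that filter through the group where it is higher alone, so the tested members may favour genes that differ. The list lay above the other genes in camera (adjusted p = 0.00391, but adjusted p = 0.39 with an estimated correlation). SPON2, S100P and TSPAN8 may have been picked by the study on these samples, so the list is not independent evidence of its own direction. FAS, a death receptor named after its values were seen, was the 1 gene that fell (4.96-fold). Among the control genes none passed the test: the log2 difference was 0.07 ± 0.25 (SE) for ACTB, 0.65 ± 0.25 for GAPDH, 0.51 ± 0.26 for TBP and 0.06 ± 0.33 for HPRT1. The sign of ACTB turned under quantile normalization, median centring, the mean of its probes, in the authors' deposited table and without vector replicate 1. That of HPRT1 turned under median centring and without MACC1 replicate 2.

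**Figure D1:**
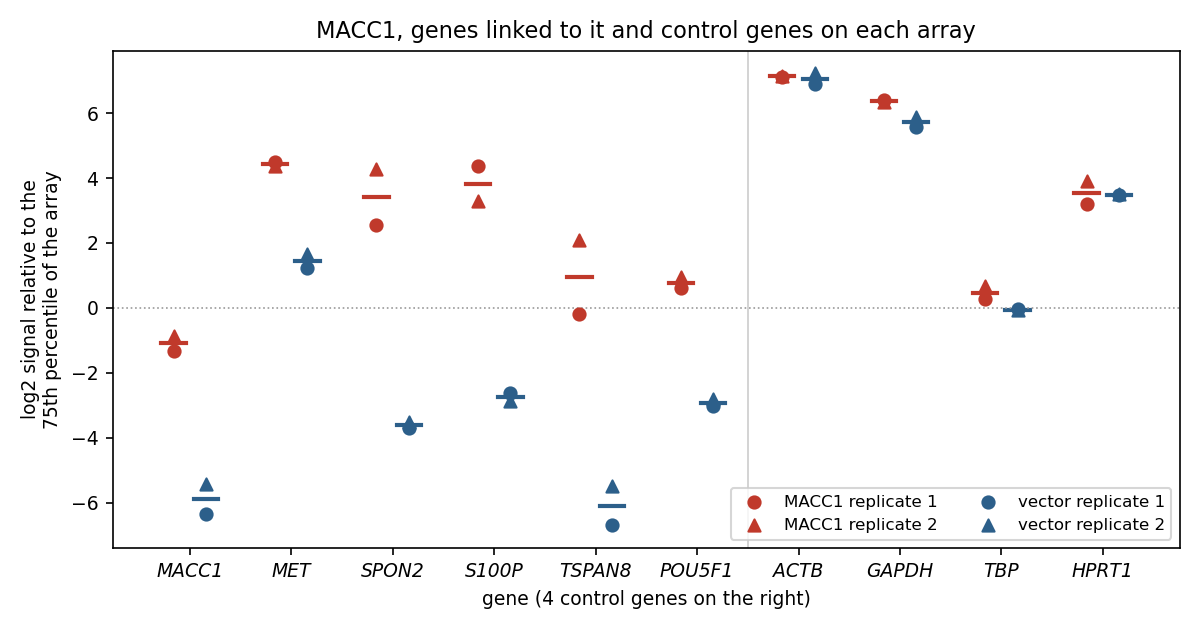
Log2 signal relative to the 75th percentile of each array (vertical axis) for MACC1, 5 genes linked to it and 4 control genes, with 1 point per array (circles replicate 1, triangles replicate 2) and a bar at each group mean of 2 arrays. MACC1 and TSPAN8 were not well above background on either vector array, so their vector points show signal that was not measured reliably; MET lies at 4.44 in MACC1 cells and 1.45 in vector cells, and ACTB at 7.13 and 7.06.

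Across the genome 1605 of the 15731 genes (10.2%) changed at an adjusted p below the threshold of 0.05, with 809 higher and 796 lower in MACC1 cells. As computed from the group means, every called gene differed at least 2-fold, the smallest by 2.26-fold, and the median was 5.51-fold. These folds include called genes with a group not well above background, where only a bound holds, so they are not exact. The bounds of ROBO4 and ESAM, both called lower, were 2.16-fold and 2.13-fold. Both MACC1 arrays lay on the same side of both vector arrays in 9748 genes (62.0%). Chance gives 33.3% for 2 samples against 2 only if all arrays vary alike. The MACC1 pair spread more than the vector pair (SD over genes of the log2 difference 1.03 against 0.41), and genes are not independent. The share that chance gives here is therefore not known and may be higher than 33.3%, so the size of any excess cannot be read from these values. In 217 of the higher genes both vector arrays, and in 191 of the lower genes both MACC1 arrays, were not well above background. Normexp gave 346 higher and 545 lower genes, a share of 38.8% higher against 50.4% in the main setting. The count rested on the closeness of the 2 vector arrays: without vector replicate 1 or without vector replicate 2 limma called 0 genes (2123 and 1948 at an unadjusted p under 0.05, against 4560 with all arrays), and without MACC1 replicate 1 or 2 it called 4873 and 6957. With no filter on dim probes it also called 0 of 30899 genes (3516 at an unadjusted p under 0.05).

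**Figure D2:**
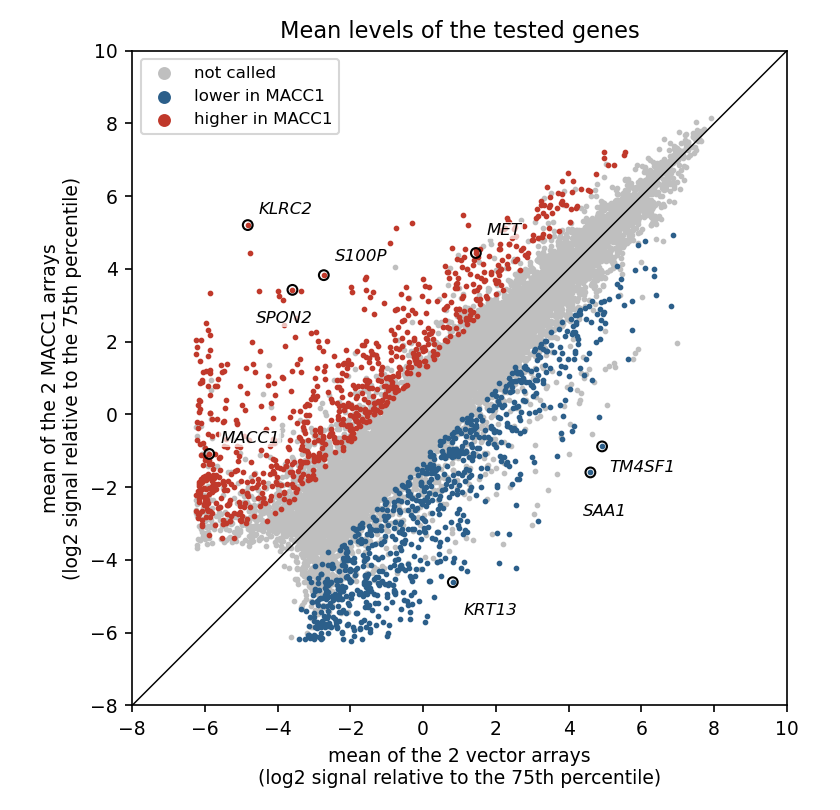
Mean log2 signal of the 2 MACC1 arrays (vertical) against that of the 2 vector arrays (horizontal), both relative to the 75th percentile of the array, with 1 point per tested gene, red for the 809 called higher, blue for the 796 called lower and grey for the rest. The line marks equal levels, and 8 genes named in the text are circled; MACC1 and KLRC2 were not well above background on either vector array and KRT13 on neither MACC1 array, so their distance from the line is not exact. MET lies at 4.44 in MACC1 cells and 1.45 in vector cells.

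The largest increases among well-expressed genes were mostly in transcripts that were not well above background in vector cells. The 4 genes KLRC2, KLRC4, KLRC1 and KLRC3, which encode lectin-like receptors of the NKG2 group known from natural killer cells, were at least 564-fold, 330-fold, 156-fold and 46.9-fold higher. Their sequences are close enough for a probe to detect more than 1 of them, so the single members are uncertain. TFF3, the trefoil peptide of goblet cells, was at least 162-fold higher (adjusted p = 0.0133), and its 2 other probes rose as well. CLRN3 was at least 87.3-fold, DACH1 at least 70.1-fold, POU2AF1 (a B-cell coactivator) at least 62.7-fold and ALB (serum albumin) at least 62.6-fold higher. GRM8, DNAJC12, PCDH19 and MYT1 were at least 55.4-fold, 51.7-fold, 48.6-fold and 42.4-fold higher. For GRM8 the 2 MACC1 arrays lay far apart, at 3.65 and 0.07, so its bound does not hold for MACC1 replicate 2 alone. ROBO1, a receptor for SLIT proteins, rose 165-fold (log2 difference 7.36 ± 0.35 SE) with 1 of 2 vector arrays well above background, and its other probe rose by 4.78. The calls of GRM8 and KLRC3 were lost with normexp.

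Among the genes with the largest decreases were SAA1 and TM4SF1. SAA1, an acute-phase apolipoprotein, fell 73.2-fold (log2 difference -6.19 ± 1.03 SE, adjusted p = 0.0386; 26.2-fold without MACC1 replicate 1 and 205-fold without replicate 2), and its near-identical neighbour SAA2 fell 68.0-fold with 1 of 2 MACC1 arrays well above background. The membrane protein gene TM4SF1 fell 55.7-fold (at -2.22 and 0.46 on the 2 MACC1 arrays), AXL, a receptor tyrosine kinase, 29.9-fold, and IGFBP3, which binds insulin-like growth factors, 28.6-fold. CACNG6, PROCR (the protein C receptor), CBR3, HSPA6, GALNT10, DKK3 and MARCHF4 fell between 29.5-fold (MARCHF4) and 72.4-fold (CACNG6), each with 1 of 2 MACC1 arrays well above background. Without MACC1 replicate 1 the falls of CACNG6, SAA2, PROCR and CBR3 were 33.5-fold, 24.3-fold, 19.6-fold and 15.1-fold. KRT13 was at least 23.1-fold, ANGPTL4 at least 18.2-fold and TKTL1 at least 26.8-fold lower. The probes of AXL and IGFBP3 lie in an area of low signal on the array of MACC1 replicate 1. Without that replicate, which leaves 1 MACC1 array, both were still lower, by -3.75 for AXL and -4.49 for IGFBP3 on the log2 scale. With all 4 arrays a second IGFBP3 probe was at -2.69.

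Targets of Wnt/beta-catenin signalling lay above the other genes in camera with the preset correlation (adjusted p = 0.000985, but adjusted p = 0.39 with an estimated correlation). Of 21 tested targets 7 rose and 0 fell over all genes, and 9 rose and 2 fell when adjusted over the list alone. CEMIP, a hyaluronan-binding protein, rose 78.1-fold, NOTUM, a secreted Wnt deacylase, 30.2-fold, the intestinal stem cell factor ASCL2 8.36-fold and NKD2 3.24-fold. For CEMIP and NOTUM 1 of 2 vector arrays was well above background. The list median was 0.97. In the list of 35 colonocyte and goblet cell genes 9 were tested, of which 4 rose and 0 fell, with the same counts when adjusted over the list alone. VIL1, the microvillus protein villin, rose 49.8-fold, CA2 (carbonic anhydrase 2) was at least 16.1-fold and MUC13 at least 3.06-fold higher, beside TFF3, and the calls of CA2 and MUC13 were lost with normexp (log2 difference 0.68 for MUC13). This list missed the threshold (camera adjusted p = 0.0599, and adjusted p = 0.573 with an estimated correlation), but passed it under median centring (adjusted p = 0.0416), with every probe, the replicate block, without either vector array and in fry (adjusted p = 0.0277). Its median was -0.07 with probes well above background on all 4 arrays.

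Of 11 metallothioneins, the cysteine-rich metal-binding proteins, 10 fell and 0 rose, over all genes and when adjusted over the list alone, and the median was -1.90. MT1F fell by 3.59 on the log2 scale (1 of 2 MACC1 arrays well above background), MT1E fell 5.41-fold, MT1M 4.67-fold and MT1L 3.94-fold, while MT3 differed by 0.88 ± 0.47 (SE) on the log2 scale and did not pass. The copies are similar enough for probes to share signal. Camera gave an adjusted p of 5.6e-06, and an adjusted p of 0.573 with an estimated correlation. Secreted matrix proteins and proteases lay below the other genes in camera with the preset correlation (median -1.14, adjusted p = 0.000593, but adjusted p = 0.39 with an estimated correlation). Of 27 members 8 fell and 3 rose, and 14 fell and 3 rose when adjusted over the list alone. SPON1 was at least 7.56-fold lower. In the other direction COL4A1, a basement membrane collagen chain, was at least 26.4-fold higher, beside SPON2.

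Interferon-response and antigen-presentation genes lay below the other genes in camera with the preset correlation (adjusted p = 0.000593, but adjusted p = 0.39 with an estimated correlation). Of 26 members 4 fell and 1 rose, and 10 fell and 2 rose when adjusted over the list alone. IFI35 fell 5.99-fold, with 1 of 2 MACC1 arrays well above background, and the immunoproteasome subunits PSMB8 and PSMB9 fell 5.63-fold and 5.13-fold. MX2, an interferon-induced GTPase, rose 5.30-fold. The list median was -0.91, and 21 members did not pass. Among 37 genes of the cell cycle and DNA replication none passed the test singly, over all genes or adjusted over the list alone, and the median was -0.43. Camera gave an adjusted p of 0.0162 for this list, and an adjusted p of 0.807 with an estimated correlation. Without MACC1 replicate 1 its median was -0.04 (adjusted p = 0.821), so that call rested on 1 array. It was also lost with normexp (adjusted p = 0.0508) and in fry (adjusted p = 0.482).

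Receptors and adhesion molecules changed in both directions. Among 22 receptor tyrosine kinases and ligands 2 rose and 2 fell, and 8 rose and 5 fell when adjusted over the list alone. FGF9 rose 3.96-fold beside MET, and EGFR fell 19.5-fold beside AXL, with 1 of 2 MACC1 arrays well above background and an adjusted p of 0.0419 that became 0.0535 under quantile normalization. In the list of 21 integrins and migration receptors 2 rose and 5 fell, and 4 and 9 when adjusted over the list alone. ITGB7 rose by 3.91 on the log2 scale, while ITGA3 fell 8.72-fold (1 of 2 MACC1 arrays well above background), the chemokine receptor gene CXCR4 6.03-fold and ITGB5 5.55-fold. In the list of epithelial junction and keratin genes 2 of 23 rose and 1 fell (5 and 1 when adjusted over the list alone), and the members that rose were JUP (2.40-fold) and CLDN7 (2.35-fold), calls lost with normexp. In the mesenchymal list 1 of 11 rose and 3 fell, and 1 and 4 when adjusted over the list alone. CCN1, a matricellular protein, fell 22.1-fold, FN1 (fibronectin) 6.62-fold and TGFBI 4.26-fold, while the smooth muscle protein gene TAGLN rose 5.97-fold with 1 of 2 vector arrays well above background, a call lost with normexp (log2 difference 1.25 against 2.58). Of 19 ERK pathway outputs 0 rose and 3 fell, and 3 rose and 4 fell when adjusted over the list alone. DUSP5, DUSP6 and SPRY4, which encode feedback inhibitors of the pathway, fell 5.82-fold, 5.63-fold and 2.86-fold, the call of SPRY4 being lost with normexp and that of DUSP6 under quantile normalization. The S100 family went both ways, with 2 of 10 higher and 1 lower, also when adjusted over the list alone. S100A14 was at least 18.4-fold higher, beside S100P, and S100A2 fell 14.2-fold (8.49-fold without MACC1 replicate 1 and 23.8-fold without replicate 2). The median of this list was -0.03, its mean 0.85 and its direction in camera upward, and the median turned to 0.05 with normexp. Camera gave adjusted p-values of 0.234 for the receptor, integrin, mesenchymal and ERK lists, 0.388 for the epithelial list and 0.542 for the S100 family, while fry called the mesenchymal (adjusted p = 0.017) and integrin lists (adjusted p = 0.0343) lower and the S100 family (adjusted p = 0.0406) higher.

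No metabolic or stress list passed camera in the main setting, while fry called the cholesterol list (adjusted p = 0.0299) and the NRF2 list (adjusted p = 0.0365) higher. In the NRF2 and xenobiotic list 5 of 17 members rose and 4 fell, and 6 and 6 when adjusted over the list alone. The aldo-keto reductase gene AKR1C3 was at least 55.9-fold and the drug efflux pump gene ABCB1 at least 12.9-fold higher (adjusted p = 0.0218; log2 difference 2.53, below that bound, and adjusted p = 0.0833 with normexp), CYP1A1 rose 9.32-fold with 1 of 2 vector arrays well above background, and HMOX1, heme oxygenase 1, fell 12.8-fold. Its median was -0.15, its mean 0.48 and its camera adjusted p 0.99. Among 27 genes of glycolysis and hypoxia 1 rose and 3 fell, also when adjusted over the list alone. HK2 (hexokinase 2) rose 2.71-fold, and ADM, P4HA2 and PFKFB3 fell 8.22-fold, 4.49-fold and 2.81-fold. Of 29 genes of cholesterol and fatty acid synthesis 1 rose and 1 fell, and 5 and 2 when adjusted over the list alone. ACACA, which encodes acetyl-CoA carboxylase, fell 2.97-fold. In the NF-kB and cytokine list the chemokine CXCL6 was the 1 of 23 genes called, at least 22.1-fold higher, and 0 were called when adjusted over the list alone. The 2 MACC1 arrays lay far apart for CXCL6 (2.08 and -1.01), and its call was lost with normexp, as were those of CYP1A1, PFKFB3 and ACACA. Of 19 immediate early genes IER5 fell 3.84-fold and none rose, and 0 rose and 3 fell when adjusted over the list alone; the median was 0.23, the mean 0.14 and the direction in camera downward. None of 26 ATF4 and unfolded protein response genes passed, over all genes or adjusted over the list alone. The camera adjusted p-values were 0.542 for glycolysis, 0.192 for cholesterol, 0.99 for NF-kB, 0.7 for immediate early genes and 0.521 for ATF4 genes. The probes of EGFR, HMOX1 and ABCB1 lie in the area of low signal, and without MACC1 replicate 1 EGFR and HMOX1 were still lower, by -3.23 and -3.85 on the log2 scale, and ABCB1 was still higher.

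Markers of other cell types were mostly not detected. Of 15 fibroblast markers 3 were tested, of which LUM was at least 4.76-fold higher and COL6A1 fell (95% interval of the fold 3.75 to 17.1). The call of LUM was lost with normexp, and so was that of ROBO4, an endothelial marker. Of 12 endothelial markers 3 were tested, of which ROBO4 and ESAM were at least 2.16-fold and 2.13-fold lower. Of 15 leukocyte markers 2 were tested and none was called. Adjusted over the list alone, 1 fibroblast marker was higher and 1 lower, 1 endothelial marker higher and 2 lower, and 0 leukocyte markers were called. Of 32 cancer-testis antigens 2 were tested, of which 0 were called over all genes and 1 was higher when adjusted over the list alone. These 4 lists had too few tested members for camera.

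**Figure D3:**
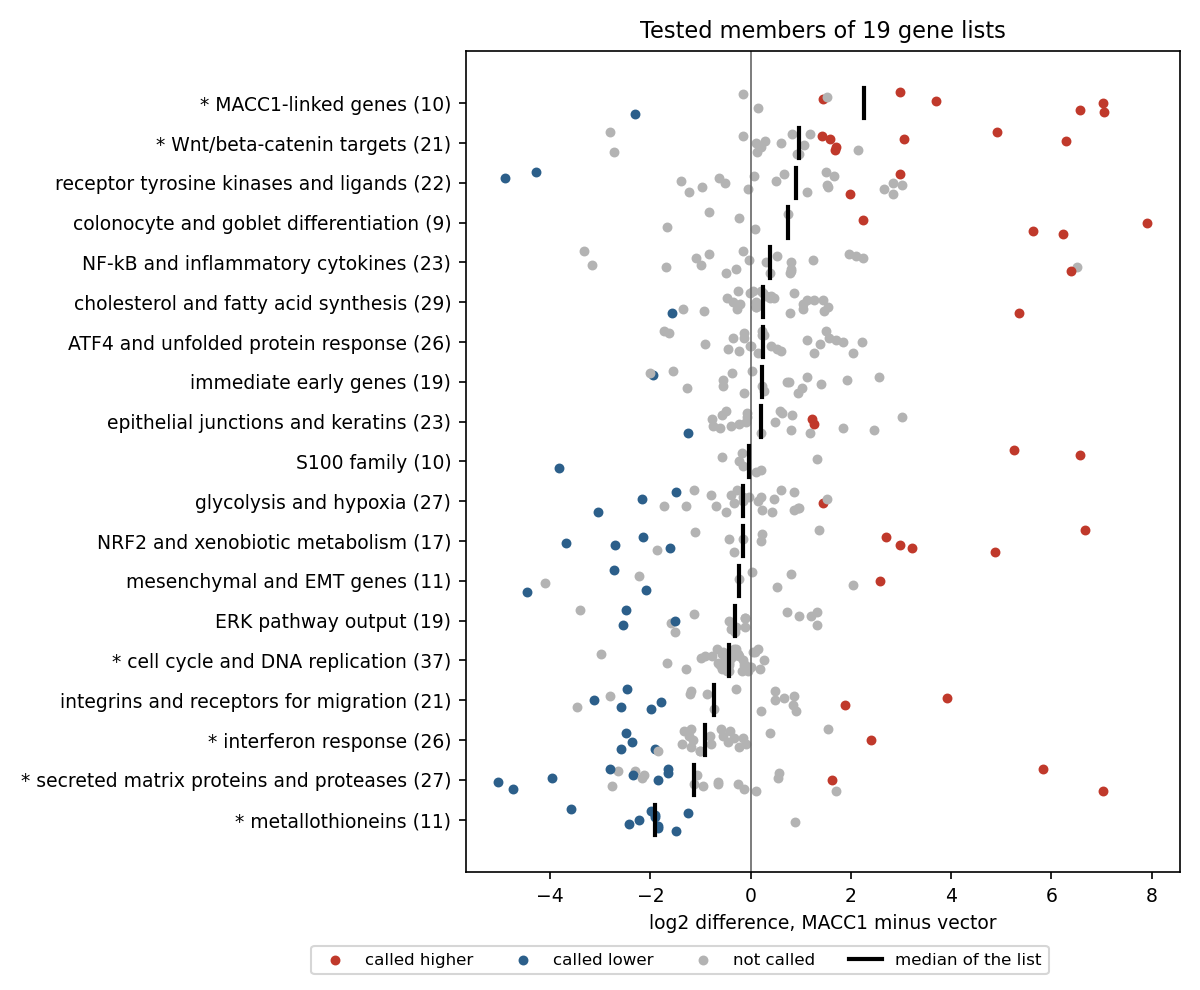
Log2 difference, MACC1 minus vector (horizontal axis), of each tested member of the 19 gene lists with at least 5 tested members, with 1 point per gene, a black bar at the list median and the number of tested members in brackets. Stars mark the 6 lists called by camera with its preset correlation of 0.01. Of these, 0 were called with an estimated correlation, a setting that also missed the list raised in the simulation. The medians run from -1.90 (metallothioneins) to 2.26 (MACC1-linked genes, with 10 of 15 members tested). Lists such as the S100 family hold members far to both sides of a median near 0.

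The 2 MACC1 arrays differed from each other more than the 2 vector arrays did. The SD over genes of the log2 difference between the arrays of a group was 1.03 for MACC1 and 0.41 for vector, and it was 0.91 and 0.41 with the area of low signal left out. Across genes, which are not independent replicates, the 2 MACC1 arrays correlated with Pearson's r = 0.927 and the 2 vector arrays with r = 0.988. Arrays of different groups correlated with r between 0.83 (MACC1 replicate 1 with vector replicate 1) and 0.9 (MACC1 replicate 2 with vector replicate 1). By this measure MACC1 replicate 2 lay nearer to vector replicate 1 than MACC1 replicate 1 did. On the array of MACC1 replicate 1, 1188 spots (2.64%) lay where the local median fell more than 1 log2 unit below the other 3 arrays, against 0 spots on MACC1 replicate 2, 0 on vector replicate 1 and 6 on vector replicate 2. Of the tested genes 336 were represented by a probe in that area, and 35 of them were called.

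**Figure D4:**
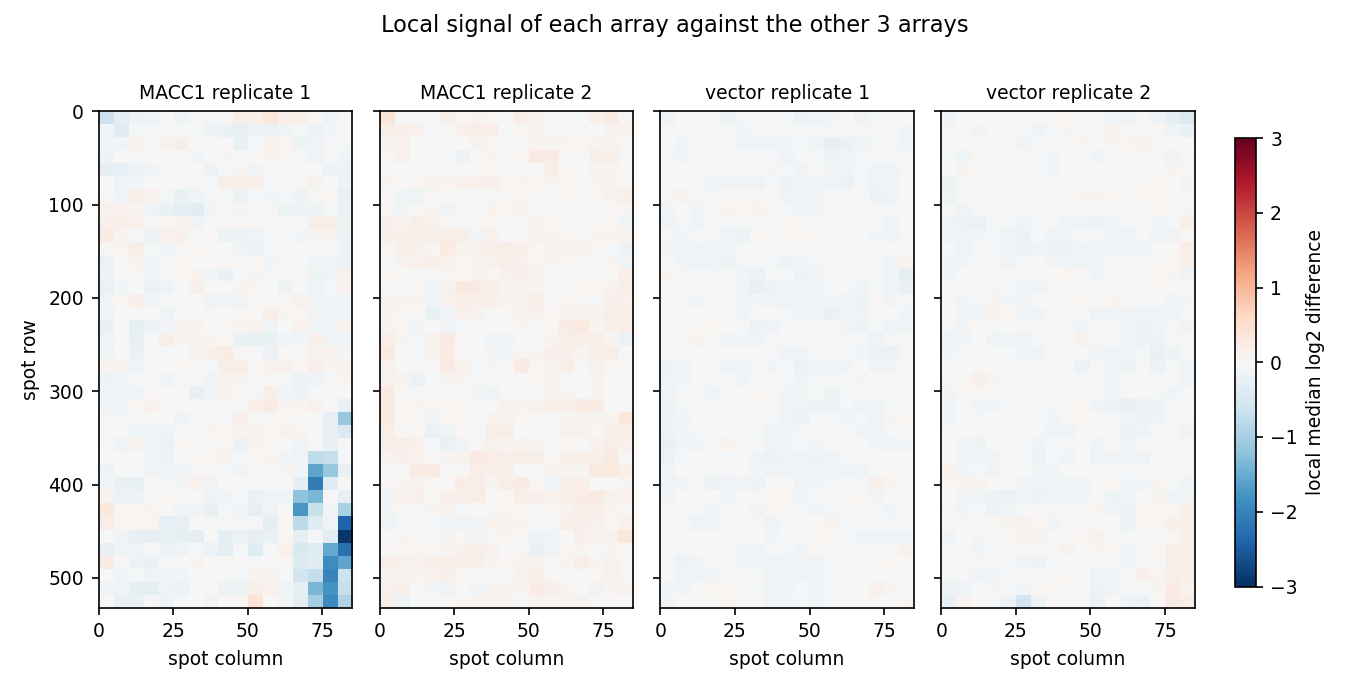
Local median of the log2 difference between each spot and the median of the other 3 arrays, by spot row (vertical) and spot column (horizontal), for the 4 arrays; blue marks signal below the other arrays. A curved area of low signal on MACC1 replicate 1 reaches from row 324 to row 532 and from column 66 to column 85, and no such area is seen on the other arrays.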

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

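The tests in this part were chosen after the pattern was seen. Spot positions, which enter no comparison, showed an area of low signal on the array of MACC1 replicate 1: 1188 spots had a local median more than 1 log2 unit below the other 3 arrays, against 0 and 6 spots on the vector arrays. The area follows a curved band near one corner, and the median spot in it was lowered by -2.48 on the log2 scale. On this array 146 probes lay at least 3 log2 units below each of the other 3 arrays although they were above the 75th percentile there; the other arrays had 2, 0 and 4 such probes. Of these probes 79.5% lay in the area, which holds 2.64% of the spots. The area was marked from the levels of the same spots, these probes included, so a part of this overlap is built in. A local loss of signal on the array surface may account for most of these probes. This reading depends on which probes count as bright, which the test had not fixed. A looser definition was run first: 493 probes well above background on the other 3 arrays and at least 3 log2 units below their median, of which 38.5% lay in the area, between the bounds of 10% and 50% and thus undecided. The stricter definition, by which the pattern had first been noticed, was taken up after that result was seen. The local loss may therefore account for most of the strict set but for a minority of the looser one, and the rest of the looser set stays open. Loss of the transcripts from the cells is argued against by the 81 other probes of the same genes outside the area, whose median difference from MACC1 replicate 2 was -0.41 on the log2 scale (quartiles -0.80 and 0.10). The 30 probes of the strict set outside the area stay open as well. No biological explanation that the design names was tested, because the area lies on 1 array.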

How the results depend on the processing

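Of the alternatives in this part, leaving out the probes in the area of low signal was chosen after seeing the data. Of the 87 named genes called, none changed direction in an alternative that tested it (40 of them with probes well above background on all 4 arrays, 82 without the area). The MACC1 level kept its direction and side of the threshold, and the counts of genes and of lists stayed within 1.5 times those reported, under quantile normalization (1459 genes), median centring (1659), the authors' table (1642), the mean of probes (1556), every probe (1642), flagged spots kept (1595), the variance trend (1638), the replicate block (1203) and without the area (1736 of 15460). The robust prior gave 1525 genes, and lists were not run under it because camera has no such option. Slide as a block was not run, since all arrays share 1 slide.

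Normexp gave 891 changed genes, 346 higher and 891 at least 2-fold, and a MACC1 difference of 1.95 (adjusted p = 0.0762); 17 named genes lost their call, ABCB1, CXCL6, CYP1A1, LUM, MUC13 and TAGLN among them, and the cause was not tested. The replicate block lost 9 of the 87 calls, quantile normalization 5 (CBR3, DUSP6, EGFR, HK2 and PROCR), flagged spots kept 1, and median centring, the authors' table, the mean of probes, every probe, the variance trend and the robust prior 2 each. Without a filter on dim probes 0 genes changed, 0 were higher, 0 lower and 0 at least 2-fold apart, and the MACC1 difference of 4.80 had an adjusted p of 0.12, 87 named genes losing their call; adjustment over 30899 genes and the noise of dim probes come with that setting. With probes well above background on all 4 arrays, 934 of 13377 genes changed, 496 higher, 438 lower and 934 at least 2-fold; MACC1 was not tested there. At thresholds of 0.1 and 0.01, 2865 and 0 genes changed. The number of lists shifted was 0 with the correlation estimated and 11 with fry, and between 5 and 9 otherwise, so single lists crossed the threshold (7 lists passed under median centring, 8 with every probe, 7 with the replicate block). The mesenchymal list passed, downward, without a filter on dim probes, with probes well above background on all 4 arrays and with every probe; the integrin list passed without that filter, and the NRF2 list, downward, with probes well above background on all 4 arrays (adjusted p = 0.0434). The NRF2 list, with a median of -0.15, turned upward in fry and passed there (adjusted p = 0.0365). The cause was not tested. The correlation that camera estimated was 0.0010 for the Wnt list, 0.0069 for the MACC1-linked list and -0.024 for the matrix list. All lie below the preset 0.01, so the loss of these calls does not come from a larger correlation. The estimate was 0.034, 0.47 and 0.59 for the interferon, metallothionein and cell cycle lists.

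Leaving out each array in turn, with the lone sample assumed to vary like the other group, gave 0 to 6957 changed genes, 0 to 3675 higher, 0 to 3282 lower and 0 to 5136 at least 2-fold. The MACC1 difference, as computed against vector signal not well above background and so without an exact size in any setting, was 4.33 to 5.26 (adjusted p = 0.174 and 0.142 without vector replicate 1 or 2). The 0 follows from the construction: without a vector array, the residual spread is that of the MACC1 pair alone. The NF-kB list ranged from -0.46 without MACC1 replicate 1 to 0.92 without replicate 2, and the immediate early genes from -1.31 to 1.78, so both turned with the MACC1 array left out. The ERK list passed, downward, without MACC1 replicate 1, and the ATF4 list, upward, without replicate 2. Signal over background limits the dim genes, where only bounds are given.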

Other observations

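The tests chosen after their results were seen in this part are the screen of gene families, the difference between the MACC1 arrays by list, and 3 of the tests of explanations: the area of low signal, the mixed sample and the abundant markers. Families were formed from symbols sharing a stem, and the 364 with at least 5 tested genes were put through camera. Besides metallothioneins, the pregnancy-specific glycoproteins stood out, secreted proteins of the carcinoembryonic antigen group known from placenta: 6 of 6 tested genes were lower (adjusted p = 6.4e-05 with the preset correlation, but adjusted p = 0.995 with an estimated correlation). All but PSG11 were not well above background on either MACC1 array, so the size of the family's fall is not known, and the test rests on signal not well above background. PSG8 was at least 16.2-fold, PSG6 at least 15.5-fold, PSG7 at least 4.51-fold and PSG9 at least 2.86-fold lower. PSG1, whose probe lies in the area of low signal, was lower too, and PSG11 fell 4.28-fold with 1 of 2 MACC1 arrays well above background. These genes are close copies whose probes can share signal. The family median stayed below 0 in all 4 other scalings. Of 5 insulin-like growth factor binding proteins 2 fell, IGFBP6 and IGFBP3, the latter with its probe in the area of low signal, and 3 did not pass (family adjusted p = 0.0265, but adjusted p = 0.995 with an estimated correlation). Of 6 tested APOBEC3 cytidine deaminase genes 4 fell and 0 rose, and this family missed the threshold (adjusted p = 0.0698).

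Stress and inflammation genes set the 2 MACC1 arrays apart from each other. The median log2 difference, MACC1 replicate 1 minus replicate 2, was 2.39 over 21 NF-kB and cytokine genes, 2.18 over 17 immediate early genes and 1.69 over 26 ATF4 and unfolded protein response genes, with the area of low signal left out. Each lay above all 10000 random lists of the same size and level, and the same lists differed by -0.12, -0.20 and -0.09 between the vector arrays. EGR2 and FOSB, immediate early transcription factors, differed by 7.19 and 5.84, the stress cytokine gene GDF15 by 6.45, DDIT4 by 5.36 and the chemokine gene CXCL3 by 4.57; these were picked after their values were seen. FOS lay at 4.67 and -0.90 on the 2 MACC1 arrays, on either side of 2.16 and 2.36 on the vector arrays. Cell cycle genes went the other way, with a median of -0.70 over 36 genes, below all random lists. The random lists were drawn gene by gene, so their genes need not move together. Camera estimated correlations of 0.64, 0.62, 0.45 and 0.59 within the NF-kB, immediate early, ATF4 and cell cycle lists. A place beyond all random lists therefore does not measure how unusual such a list is. The medians of the MACC1-linked list (-0.10) and of the Wnt/beta-catenin targets (0.03) lay near 0 with members going both ways, so they do not show that these genes were alike on the 2 arrays. The sign of the Wnt median turned with median centring. As values of single arrays these describe the 2 samples and have no test between cultures.

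The larger spread of the MACC1 pair, with an SD over genes 2.51 times that of the vector pair, was weighed against 3 technical explanations. Local loss of signal on the array surface is argued against as the whole cause, because the ratio was still 2.20 with the area left out. Vector-type cells mixed into MACC1 replicate 2 would place it between the groups: 151 genes at least 16-fold lower on MACC1 replicate 1 would need a vector share of 7.88% (quartiles 3.22% and 12.3%), whereas 285 genes at least 16-fold higher would leave a MACC1 share of 31.4% (quartiles 16.8% and 59.9%), and the sum of 39.2% is far from 100%. The genes were picked on MACC1 replicate 1, which lowers the share from the higher genes. FOS, EGR2 and FOSB were each higher than in vector cells on MACC1 replicate 1 and lower than in vector cells on replicate 2. They were picked after their values were seen, so they do not decide the question. On replicate 2 CCL2 (-0.96) and CXCL8 (-2.31) lay near their vector levels (-0.94 and -1.02, and -2.27 and -2.26). A narrower response to RNA amount is argued against by the spike-in series, whose slope on MACC1 replicate 2 was 0.992 times that on MACC1 replicate 1. A difference in the state of the cells at harvest may underlie the lists above, but the labels record none, so no biological explanation was tested.

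The number of genes that differ, with 4139 (26.3%) at least 2-fold apart in their means, was weighed in the same way. Chromosome-scale differences between the cell populations, as clones of one line can carry, would make distant neighbours move together. Over 10730 autosomal genes, log2 differences of genes 10 to 50 positions apart correlated with r = 0.0696. This lay above the highest of 1000 permuted gene orders (0.00515) and was 6.38 times the value for the difference between the vector arrays (0.0109). Differences within a group passed the permutation too: 0.0109 between the vector arrays (highest permuted 0.00463) and 0.0135 between the MACC1 arrays (0.00531). Neighbours thus also moved together where no populations are compared, so this test cannot tell chromosome-scale differences from other causes. Such differences stay possible for a part of the changes, but a correlation of this size leaves most of the variation between genes open. MACC1 itself, named by the design, stays open and untested as a cause. Cells of another type mixed into the MACC1 cultures were tested by 42 fibroblast, leukocyte and endothelial markers. The test set beforehand left this undecided, because 1 of 6 detected markers (16.7%) was higher, between the bounds of 10% and 50%. In a test added later, 0 of 7 abundant markers (COL1A1, COL1A2, COL3A1, PTPRC, LCP1, PECAM1 and VWF) were well above background on both MACC1 arrays. Because this test was added after the levels were seen, it cannot decide the question. Of all 42 markers, 5 were well above background on both MACC1 arrays and 6 on both vector arrays. Markers of fibroblasts, leukocytes and endothelial cells also cannot test for other epithelial cells.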
